A study of Mus musculus with 4 samples.

How the data were processed

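Polyadenylated RNA of flow-sorted leukemia stem cells was sequenced with a kit that marks the strand by dUTP, per the labels' protocols. Each of the 4 libraries, 2 per genotype, was made from a pool of cells of 4 mice. The authors deposited 1 table of FPKM values per gene and library, per the file headers. The submitters' processing notes name Trimmomatic 0.32 and the genome build GRCm38.p4. The aligner, the quantification tool, its annotation and its use of strand are not given in the sources used here, so reads of overlapping genes may be shared. Of the 45786 genes, 45137 (98.6%) were matched to GENCODE M21 by gene identifier without version, from which gene types and coordinates on GRCm38 were taken. Among the tested genes that are reported, Car1, Cdt1, Ctss, Gclm, Hoxa9, Itga2b, Mcpt8, Meis1, Mir2861, Mir3082, Ramp2, Slc2a3, Stx8 and Tcf7 overlap another annotated gene on the same strand. App, Cd34, Cxcl10, Cyba, Fn1, Gfi1, Gpx2, Hk3, Il18, Irf7, Mpo, Ncf1, Ndrg1, Pcx, Pfkp, Plvap, Prtn3, Rnu11, Selp and Wfdc12 overlap one on the opposite strand only.

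FPKM carry no read counts, and whole reads were not recovered from them, so no count model was used and no counting intervals are given. Values under 0.5 FPKM fell on steps whose most common log2 ratio to wild type replicate 1 was 0.04 for wild type replicate 2, 0.03 for NOX2-KO replicate 1 and -0.2 for NOX2-KO replicate 2. None of 197 ribosomal protein, oxidative phosphorylation, glycolysis and tricarboxylic acid cycle genes was at 0 in any library. Where a group was listed at 0 in both libraries, the values of each library are given and no ratio. Across the 12253 tested genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.96 between the wild type libraries, 0.93 between those labelled NOX2-KO and 0.899 to 0.911 between groups.

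Genes with a mean FPKM of at least 1 over the 4 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of variance on mean expression, 2 residual and 3.28 prior degrees of freedom). Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Fold changes are the libraries labelled NOX2-KO minus wild type on that scale. Where they are given relative to all genes, the median over all tested genes (-0.19) was subtracted. The SE and the adjusted p are those of the fitted change before this subtraction. Camera, a competitive test of a gene set against the other genes, was run with a preset inter-gene correlation of 0.01 on lists with at least 5 tested genes, 30 of 33, adjusted over the lists. The 33 lists hold 826 entries, of which 825 were found. For a symbol that names more than 1 row, the row with the highest mean was used. The groups, lists, tests and alternatives were fixed before the data were examined.

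Genes were named by a rule fixed at the same time. The rule took Cybb, then the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, without predicted genes and pseudogenes, then per list up to 4 members with the smallest p, and a fixed set of 17 genes including Foxc1, Mpo, Elane, Hoxa9 and the NADPH oxidase partners. Of list members outside the fixed set, only those past the threshold were named, except Cd4, Cd8a, Cd5 and Cd6, which were chosen after their values were seen. A few genes that the rule took are not reported here.

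On simulated data with the means and spreads of these 12253 genes, in 10 runs with 200 changed genes each, drawn from those with a wild type mean above 2 on the log2(FPKM + 1) scale, the gene test recovered 18.8% of genes changed by 1 log2 unit, 86.4% of those changed by 2 and 95.8% of those changed by 3, and 5% of its calls were false. Recovery of changes in genes below that level was not simulated. Variances were drawn in the form that limma assumes, equal in both groups, and no shift of all genes was simulated. In the data the median absolute log2 difference was 0.298 between the libraries labelled NOX2-KO and 0.18 between the wild type ones. The simulated 5% is therefore not the rate of false calls in the data. The set test called the changed list in 10 of 10 runs and 0 of 20 unchanged lists. Simulated genes were drawn independently of each other, while the estimated correlation in the data reached 0.967 for ribosomal proteins. These counts therefore do not give the rate of false calls for lists whose genes move together. Alternatives were a pseudocount of 0.1, no filter on low values, a minimum mean of 5 FPKM, scaling by a trimmed mean of log ratios (TMM, 30% and 5% trimmed, computed on the FPKM), quantile normalization, a replicate block, no variance trend, each library left out in turn, an adjusted p of 0.1, an added 2-fold threshold, camera with an estimated correlation, and limma's rotation test fry. With an estimated correlation camera tests on the 2 residual degrees of freedom, with the preset one on nearly as many as there are genes. Rescaling to protein-coding genes was added after seeing the data. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.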

Results

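RNA from sorted leukemia stem cells was sequenced in 4 libraries. The cells came from mice that carried a leukemia driven by the NUP98/HOXA9 and BCR/ABL fusion genes. In 2 libraries the leukemia was wild type and in 2 it was labelled as a knockout of NOX2, the superoxide-producing NADPH oxidase whose catalytic subunit gp91phox is encoded by Cybb. Each library was made from cells pooled from 4 mice, and the labels call the 2 pools of a genotype technical replicates. P-values here therefore measure only the spread between these pools, which may be technical. The deposited values are FPKM, fragments normalised to transcript length and to the mapped fragments of the library. They summed to 595003 and 642081 in wild type and to 635048 and 510920 in the libraries labelled NOX2-KO. Read depth is not given, and 12253 of 45786 genes had a mean of at least 1 FPKM and were tested.

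The comparison asks how loss of NOX2 changes the transcriptome of these cells, and the targeted gene was read first. Cybb (ENSMUSG00000015340.8, chromosome X, 9435252 to 9487771, minus strand, GRCm38, GENCODE M21) was at 1.22 and 1.01 FPKM in wild type and at 7.26 and 10.4 FPKM in the libraries labelled NOX2-KO. It was thus higher, not lower, in the libraries labelled knockout, by 2.40 ± 0.27 log2 units (SE) relative to all genes, with a limma adjusted p of 0.0207. A gene-level FPKM cannot show a disrupted part of a gene, so these values neither establish nor exclude the knockout, and every direction given here is that of the libraries as labelled. Among the partners of gp91phox, Ncf1 (p47phox) fell from 142 ± 4.10 to 71.7 ± 0.193 FPKM (mean ± SD, n = 2 each), a change of -0.78 ± 0.14 log2 units (SE) relative to all genes. Its limma adjusted p was 0.0277, and 0.0559 after TMM scaling. Cyba and Ncf4 did not pass the test: Cyba was at 322 and 344 FPKM on average in wild type and in the libraries labelled NOX2-KO, and Ncf4 at 93.8 and 101. In the list of NADPH oxidase subunits, which leaves out Cybb, 0 of 8 tested members rose and 1 fell, with the same counts adjusted over the list alone.

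**Figure D1:**
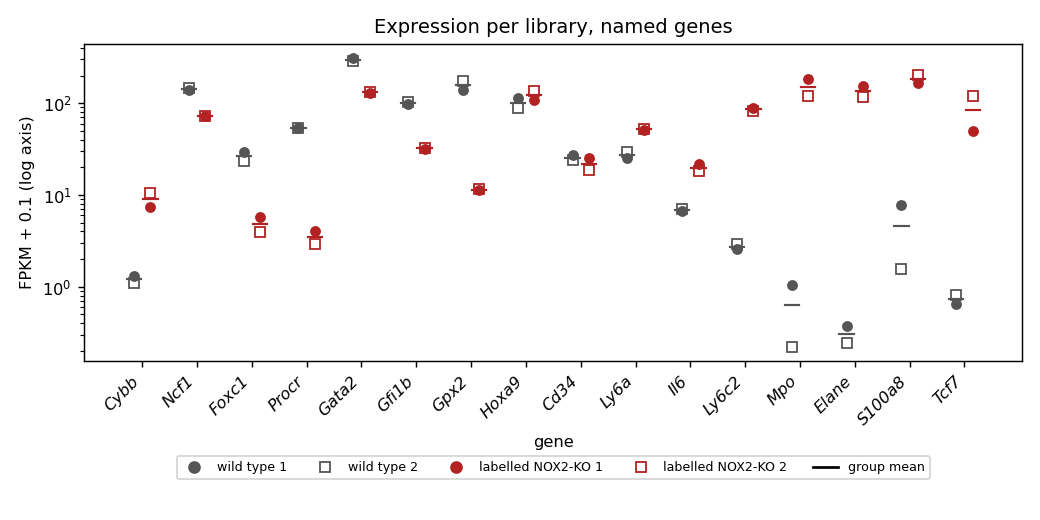
FPKM + 0.1 on a log axis for 16 named genes in each library. Grey symbols are wild type, red symbols the libraries labelled NOX2-KO, circles replicate 1, squares replicate 2, and short lines group means. Cybb was at 7.26 and 10.4 FPKM in the libraries labelled NOX2-KO and near 1 in wild type, while Mpo, Elane and Tcf7 went from under 1 FPKM to 49.8 or more.

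In the libraries labelled NOX2-KO, 4 of 10 primary granule genes, 5 of 20 late neutrophil genes, 5 of 13 T cell markers and 4 of 27 cytokines and NF-kB targets rose. Camera called each of these lists higher with its preset correlation. It called none with an estimated correlation, where it tests on only 2 degrees of freedom and the lowest adjusted p was 0.28. The rotation test fry called none of them either, with an adjusted p of 0.06 for each. Fry tests members alone, so the negative median change of all tested genes, given below, counts against lists that rose. Foxc1 fell, as did 2 of 19 fatty acid oxidation genes and 3 of 23 glycolysis genes. In total 530 genes passed a limma adjusted p of 0.05, of which 177 were higher and 353 lower in the libraries labelled NOX2-KO. The median log2 change of all tested genes was -0.19, and 0.01 after TMM scaling, so single changes are given relative to that median. Their adjusted p are those of the fitted changes before it was subtracted. The log2(FPKM + 1) scale understates the change of low genes. With the shift removed the split became even: 208 genes higher and 205 lower after TMM scaling, and 220 and 242 after quantile normalization. No gene passed when any 1 of the 4 libraries was left out, where 1309 to 3513 genes had an unadjusted p under 0.05. Without a filter on low values none passed either, and 3872 had an unadjusted p under 0.05. Each of the 530 genes that could be tested kept its direction in all these fits.

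The largest rises were in neutrophil and lymphoid genes. Elane (neutrophil elastase) went from 0.208 ± 0.0928 to 135 ± 26.3 FPKM (mean ± SD, n = 2); its limma adjusted p was 0.00224. Mpo (myeloperoxidase) went from 0.528 ± 0.573 to 151 ± 46.6 FPKM, a change of 6.85 ± 0.35 log2 units (SE). S100a9 and S100a8, the subunits of calprotectin, reached 122 ± 36.1 and 183 ± 25.6 FPKM from 1.46 ± 1.71 and 4.54 ± 4.38. Ngp, an antimicrobial granule protein, reached 74.4 ± 44.3 FPKM. Camp, the cathelicidin precursor, was listed at 0 in both wild type libraries and at 21 and 50.2 FPKM in the others. Stfa1, a stefin of a family with near-identical copies, was likewise listed at 0 in wild type and at 37.9 and 27.6 FPKM. Tcf7, a transcription factor of early T cells, rose from 0.626 ± 0.117 to 84 ± 48.3 FPKM, and Ly6d, a surface marker of early lymphoid cells, from 0.461 ± 0.189 to 74.7 ± 27.2. Trbc1, a T cell receptor beta constant segment with a close copy in the genome, was at 27.9 and 42.8 FPKM against 0.552 and 0. The 12 largest rises also held the microRNA genes Mir3082 and Mir2861, which lie within Stub1 and Cdk9 on the same strand, so their reads cannot be told from those of the host genes.

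Among protein-coding genes the largest falls were of Ramp2, a partner protein of the calcitonin receptor-like receptor, at 78.1 and 89.4 FPKM in wild type and at 0 and 0.707 in the libraries labelled NOX2-KO, and of Stx8, an endosomal syntaxin, at 36.2 and 55.3 FPKM against 0 and 0.144. A listed 0 can be a failed estimate. Ramp2 overlaps Vps25 and Stx8 overlaps Gm26157 on the same strand, so their reads may be shared. Ctse (cathepsin E) fell from 62 ± 2.73 to 0.791 ± 0.226 FPKM, a change of -4.95 ± 0.19 log2 units (SE) with an adjusted p of 0.00228. Aldh1a2, which makes retinoic acid, fell from 28.4 ± 1.08 to 0.193 ± 0.109 FPKM, and Gpx2, a glutathione peroxidase, from 157 ± 25.8 to 11.3 ± 0.148. Procr, the endothelial protein C receptor and a marker of hematopoietic stem cells, fell from 53.7 ± 0.596 to 3.37 ± 0.774 FPKM, a change of -3.46 ± 0.19 log2 units. App, Wfdc12, Plscr2 and the vesicular glutamate transporter gene Slc17a8 fell to means between 0.272 and 1.06 FPKM. The small RNA genes mt-Tn and Rnu11 were listed at 0 in both libraries labelled NOX2-KO, and FPKM of such short genes are poorly defined. Foxc1 (ENSMUSG00000050295.3, chromosome 13, 31806633 to 31812476, plus strand, GRCm38), a mesenchymal transcription factor, fell from 26.2 ± 4.10 to 4.70 ± 1.25 FPKM, a change of -2.07 ± 0.24 log2 units with an adjusted p of 0.0152.

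**Figure D2:**
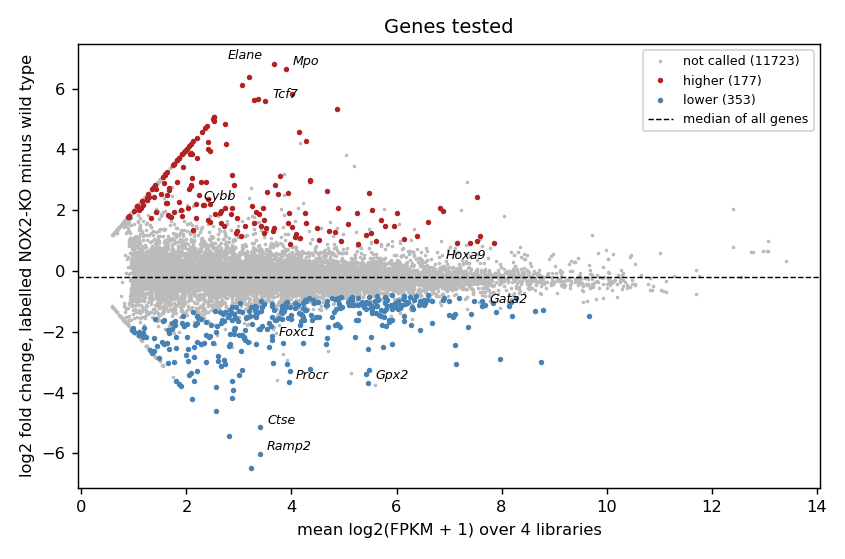
Log2 fold change of each of the 12253 tested genes, libraries labelled NOX2-KO minus wild type, against the mean log2(FPKM + 1) over the 4 libraries. Red points are the 177 genes called higher, blue points the 353 called lower, grey points the rest, and the dashed line is the median of all genes at -0.19; after TMM scaling the calls were 208 higher and 205 lower.

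Among the gene lists fixed beforehand, the tested markers of several blood lineages were higher as sets in the libraries labelled NOX2-KO. The late neutrophil list holds 32 genes, the mast cell list 19, the T cell list 17, the NK cell list 13 and the monocyte list 23. Members with a mean under 1 FPKM over the 4 libraries were not tested. A gene near 0 in wild type was thus tested only if it was higher in the others, so these counts do not describe whole lineage programmes. Of 10 primary granule genes 4 rose and none fell, 5 and 2 adjusted over the list alone. Prtn3 (proteinase 3) went from 3.40 ± 0.0438 to 88.4 ± 40.8 FPKM and Ctsg (cathepsin G) from 9.27 ± 1.06 to 70.1 ± 44.1, beside Mpo and Elane. Camera's adjusted p for this list was 5.79e-05, and its adjusted p = 0.55 with an estimated correlation. Of 20 late neutrophil genes 5 rose and none fell, 13 and 2 adjusted over the list alone, and 1 fell after quantile normalization. Those that rose held Camp, Ngp, S100a8 and S100a9, while Ltf (lactoferrin) was at 6.78 ± 2.06 and 8.19 ± 8.39 FPKM and did not pass. The camera adjusted p of that list was 1.49e-11, and its adjusted p = 0.28 with an estimated correlation. Of 16 mast cell, basophil and eosinophil markers 7 rose and 1 fell, 9 and 1 adjusted over the list alone (camera adjusted p = 3.08e-11, and adjusted p = 0.28 with an estimated correlation). Fcer1a, a chain of the IgE receptor, rose from 6.24 ± 0.713 to 56.9 ± 3.97 FPKM and the basophil protease gene Mcpt8 from 59.4 ± 8.24 to 235 ± 25.4. Prg2, the eosinophil major basic protein, rose from 0.64 ± 0.531 to 28.4 ± 8.81 FPKM, while Siglecf fell from 53.8 ± 4.06 to 11.2 ± 2.96.

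Of 13 T cell markers 5 rose, 10 adjusted over the list alone, and none fell (camera adjusted p = 1.05e-12, and adjusted p = 0.298 with an estimated correlation). Beside Tcf7 these held Bcl11b, a factor of T lineage commitment, at 7.67 and 17.2 FPKM against 0.0012 and 0.356. The adhesion receptor gene Cd2 was at 7.16 ± 2.40 FPKM against 0.259 ± 0.23, and Cd3g, a chain of the T cell receptor complex, at 8.35 and 12.9 against 0 listed in both wild type libraries. Cd4 and Cd8a, markers of more mature T cells, were at or under 0.514 FPKM in every library. Of 6 NK cell markers 3 rose and 1 fell, 4 and 1 adjusted over the list alone (camera adjusted p = 0.00419, and adjusted p = 0.298 with an estimated correlation). Gzmb (granzyme B) rose from 54.1 ± 6.32 to 238 ± 72.9 FPKM and Il2rb from 0.289 ± 0.0838 to 9.20 ± 4.29. Gzma was listed at 0 in wild type and at 10.6 and 14.2, and Klrb1c (NK1.1) fell from 12.5 ± 0.024 to 0.28 ± 0.122. Of 8 monocyte and macrophage genes 4 rose and 1 fell, 5 and 2 adjusted over the list alone (camera adjusted p = 0.00153, and adjusted p = 0.297 with an estimated correlation). Ly6c2, a marker of inflammatory monocytes, rose from 2.64 ± 0.262 to 85.8 ± 4.52 FPKM, the chemokine receptor gene Ccr2 from 4.43 ± 0.484 to 19.4 ± 6.21. Ctss (cathepsin S) rose from 0.988 ± 0.0675 to 10.5 ± 3.67 FPKM, while Apoe (apolipoprotein E) fell from 137 ± 11.6 to 14 ± 5.24. Of 14 myeloid transcription factors 2 rose and 1 fell, 5 and 3 adjusted over the list alone (camera adjusted p = 0.00288, and adjusted p = 0.421 with an estimated correlation). Gfi1, a repressor needed for granulocyte formation, rose from 1.45 ± 1.09 to 11.1 ± 2.27 FPKM and Egr1 from 103 ± 6.56 to 196 ± 10.2, and Foxc1 was the member that fell. Cebpe was at 0.123 ± 0.174 and 3.42 ± 2.54 FPKM and Cebpa at 0.829 ± 0.142 and 1.67 ± 0.62, and neither passed, though Cebpe did among protein-coding genes only (0.0214), a setting chosen after seeing the data. Without NOX2-KO replicate 1 the call of the transcription factor list ended (camera adjusted p = 0.0815). The share of FPKM from ribosomal RNA genes moved with these lists, from 1.25% and 1.78% in wild type to 4.14% and 3.43% in the libraries labelled NOX2-KO.

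Inflammatory and interferon genes were also higher as sets in the libraries labelled NOX2-KO. Of 27 cytokines and NF-kB targets 4 rose, 10 adjusted over the list alone, where 3 also fell (camera adjusted p = 0.000272, and adjusted p = 0.28 with an estimated correlation). After TMM scaling and after quantile normalization 7 rose and none fell. Il6 (interleukin 6) rose from 6.74 ± 0.232 to 19.8 ± 2.45 FPKM, by 1.61 ± 0.18 log2 units (SE) with an adjusted p of 0.0231. Il18 rose from 0.252 ± 0.254 to 7.33 ± 1.99 FPKM, Ccl4 from 122 ± 5.0 to 229 ± 15.7, and Nfkbia, the inhibitor that NF-kB induces, from 167 ± 2.71 to 319 ± 5.02. Of 28 interferon response genes 4 rose and 1 fell, 16 and 1 adjusted over the list alone (camera adjusted p = 3.08e-11, and adjusted p = 0.28 with an estimated correlation), and 7 rose after quantile normalization. Cxcl10 rose from 6.40 ± 1.27 to 56.9 ± 11.1 FPKM, Irf7 from 5.23 ± 0.0286 to 18.8 ± 1.72 and Isg15 from 6.01 ± 1.09 to 17.7 ± 3.31. The RNA sensor gene Ifih1 fell from 18.8 ± 2.95 to 7.12 ± 0.115 FPKM, a fall whose adjusted p was 0.0534 after TMM scaling. None of 22 immediate early and handling stress genes passed the gene test, over all genes or adjusted over the list alone, though 2 rose after TMM scaling and 2 after quantile normalization. The list was higher as a set (camera adjusted p = 0.000464, and adjusted p = 0.421 with an estimated correlation), and it leaves out Egr1, an immediate early gene that rose and stands among the myeloid transcription factors.

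Of 34 stem cell and self-renewal genes 2 rose and 3 fell in the libraries labelled NOX2-KO, 5 and 13 adjusted over the list alone. The list did not pass as a set (camera adjusted p = 0.282), though it did as lower without a filter on low values (0.0389). That setting compares a list with 25422 genes, whose median change was -0.013, against -0.19 over the 12253 tested ones. The shift shared by the tested genes therefore counts toward a lower call there. Procr, Gfi1b and Gata2, the last 2 being transcription factors of early progenitors, fell. The values of Gfi1b were 100 ± 2.06 and 32.1 ± 0.359 FPKM and those of Gata2 296 ± 15.8 and 132 ± 2.61. Tcf7, which the T cell list also holds, rose, and so did Ly6a (Sca-1), from 27.4 ± 2.78 to 51.8 ± 1.50 FPKM. HOXA9 is also part of the fusion that drives the leukemia, so reads of the fusion may be counted in Hoxa9. Hoxa9 was at 102 ± 17.9 and 123 ± 19.2 FPKM, Meis1 at 25.9 ± 3.11 and 14.8 ± 0.216, Cd34 at 25.4 ± 2.13 and 21.8 ± 4.75, and Kit at 4.25 ± 3.32 and 14.4 ± 6.38. None of these 4 passed, with limma adjusted p of 0.463, 0.0729, 0.548 and 0.161, though Meis1 did at a minimum mean of 5 FPKM (0.0438) and Kit with a replicate block (0.0402). Of 13 megakaryocyte and platelet markers 3 fell, 5 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0831), though it did as lower after TMM scaling (0.0184), after quantile normalization (0.018), among protein-coding genes only (0.00867) and without NOX2-KO replicate 1 (0.0096). Its adjusted p = 0.636 with an estimated correlation. Selp (P-selectin) fell from 15.1 ± 3.16 to 1.34 ± 0.526 FPKM, Itgb3 from 25.2 ± 0.75 to 8.64 ± 0.695 and Itga2b (CD41) from 305 ± 4.77 to 139 ± 17.4, the last with an adjusted p of 0.0514 after TMM scaling. Of 9 erythroid markers Car1 (carbonic anhydrase 1) rose, from 13.5 ± 1.78 to 62 ± 22.5 FPKM. It was also the 1 call adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0841). It passed as higher without NOX2-KO replicate 2 (0.000621) and at a minimum mean of 5 FPKM (0.0339), and its direction turned without NOX2-KO replicate 1 (0.895). Of 24 antioxidant enzymes Gclm, the modifier subunit of glutamate-cysteine ligase, fell, from 278 ± 10.3 to 138 ± 12.7 FPKM with an adjusted p of 0.067 after TMM scaling. The list leaves out Gpx2, whose fall is given above and had a limma adjusted p of 0.0043 after TMM scaling. Adjusted over the list alone 4 fell, and the list did not pass (camera adjusted p = 0.287). It passed as lower without a filter on low values (camera adjusted p = 0.0192), against the same wider set of genes. Its mean z-score of members minus other genes was -1.11 without NOX2-KO replicate 1. Without NOX2-KO replicate 2 its direction turned, at 0.01.

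The fatty acid oxidation, glycolysis, hypoxia, tricarboxylic acid cycle and ribosomal protein lists were lower as sets in the libraries labelled NOX2-KO, with medians of -0.37 to -0.11 log2 units relative to all genes. Of 19 fatty acid oxidation genes 2 fell, 5 adjusted over the list alone, with a median of -0.29 log2 units relative to all genes (camera adjusted p = 0.000651, and adjusted p = 0.28 with an estimated correlation). Acaa2, an enzyme of mitochondrial beta-oxidation, fell from 73.2 ± 0.722 to 32.4 ± 2.38 FPKM. Of 23 glycolysis genes 1 rose and 3 fell, 1 and 8 adjusted over the list alone (camera adjusted p = 0.0279, and adjusted p = 0.636 with an estimated correlation). Pfkp and Pfkl, subunits of phosphofructokinase, fell from 104 ± 3.63 to 33.7 ± 2.92 and from 91.9 ± 2.45 to 42.9 ± 3.72 FPKM, and the glucose transporter gene Slc2a3 from 74.7 ± 6.98 to 27.7 ± 1.62. Hk3, a hexokinase of myeloid cells, rose from 2.78 ± 0.457 to 13.1 ± 4.12 FPKM. Of 17 hypoxia response genes 2 fell, 6 adjusted over the list alone (camera adjusted p = 0.027, and adjusted p = 0.345 with an estimated correlation). P4ha1 fell from 14.2 ± 3.56 to 4.19 ± 0.724 FPKM and Ndrg1 from 80.3 ± 6.07 to 32.9 ± 9.21, with adjusted p of 0.0664 and 0.075 after TMM scaling, and no member of the list passed after quantile normalization. Of 26 tricarboxylic acid cycle genes Pcx (pyruvate carboxylase) fell, from 14.2 ± 1.82 to 5.60 ± 0.279 FPKM with an adjusted p of 0.068 after TMM scaling, and no member passed after quantile normalization. Adjusted over the list alone 2 fell, and the list was lower as a set (camera adjusted p = 0.0126, and adjusted p = 0.421 with an estimated correlation). No member of the 76 ribosomal proteins passed, over all genes or adjusted over the list alone, and the list was lower as a set (camera adjusted p = 0.0295, and adjusted p = 0.893 with an estimated correlation). Some of these calls ended under other settings. With a replicate block the glycolysis list (camera adjusted p = 0.0885) and the ribosomal list (0.183) did not pass. The tricarboxylic acid list did not pass after TMM scaling (0.145), after quantile normalization (0.297), among protein-coding genes only (0.314), at a minimum mean of 5 FPKM (0.0615) or without WT replicate 2 (0.0865). The glycolysis list did not pass without WT replicate 1 (0.0558), WT replicate 2 (0.128) or NOX2-KO replicate 2 (0.0657), nor the hypoxia list without NOX2-KO replicate 1 (0.0672) or replicate 2 (0.0603) or at a minimum mean of 5 FPKM (0.0662). The ribosomal list did not pass at a minimum mean of 5 FPKM (0.119), without WT replicate 2 (0.924) or, with its direction turned, without NOX2-KO replicate 2 (0.209).

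In the libraries labelled NOX2-KO Cdt1, a licensing factor among 39 DNA replication genes, rose from 10.5 ± 0.357 to 20.3 ± 0.647 FPKM. No member passed adjusted over the list alone, and the list was higher as a set (camera adjusted p = 1.76e-05, and adjusted p = 0.28 with an estimated correlation). The 37 mitosis genes held no call and did not pass as a set (camera adjusted p = 0.777). Neither did the 71 oxidative phosphorylation subunits (0.478), the 28 ribosome biogenesis genes (0.442) or the 27 cholesterol and fatty acid synthesis genes (0.828). The 10 pentose phosphate pathway genes (0.445), the 23 unfolded protein and stress response genes (0.754) and the 9 neighbours of Cybb on the X chromosome (0.51) did not pass either. None of these 7 lists held a call over all genes or adjusted over the list alone. The oxidative phosphorylation list passed as lower without NOX2-KO replicate 1 (camera adjusted p = 8.37e-09) and as higher without NOX2-KO replicate 2 (0.00015), so these libraries moved it in opposite directions. With all libraries its estimated correlation between genes was 0.88, far above the preset 0.01, and its adjusted p = 0.902 with an estimated correlation. The ribosome biogenesis list was also lower without NOX2-KO replicate 1, with a mean z-score of members minus other genes of -0.97. Both lists passed as lower without a filter on low values (camera adjusted p = 0.0254 and 0.0217). There the other genes had a median change of about -0.013, so a list that shares the shift of tested genes can pass as lower. With the filter the medians of these lists lay at -0.016 and 0.009 relative to all genes. Of 21 p53 target genes Btg2 rose from 33.9 ± 3.12 to 68 ± 7.20 FPKM and Perp fell from 29.1 ± 1.14 to 11.4 ± 0.0997, with the same counts adjusted over the list alone and a camera adjusted p of 0.287. The 6 tested MHC class II and dendritic cell genes held no call over all genes and 3 falls adjusted over the list alone, and the list passed as lower after TMM scaling (camera adjusted p = 0.0349) but not before (0.0736), and without NOX2-KO replicate 1 (0.023). The B cell, stromal and sex-linked lists had 4, 4 and 2 tested genes, too few for a set test. Ighm, an immunoglobulin constant gene, rose from 0.149 ± 0.166 to 17.4 ± 11.8 FPKM. Fn1 (fibronectin) and Plvap fell from 17.4 ± 1.11 to 1.13 ± 0.00125 and from 48.4 ± 4.64 to 4.16 ± 1.46. Neither of the tested sex-linked transcripts passed.

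**Figure D3:**
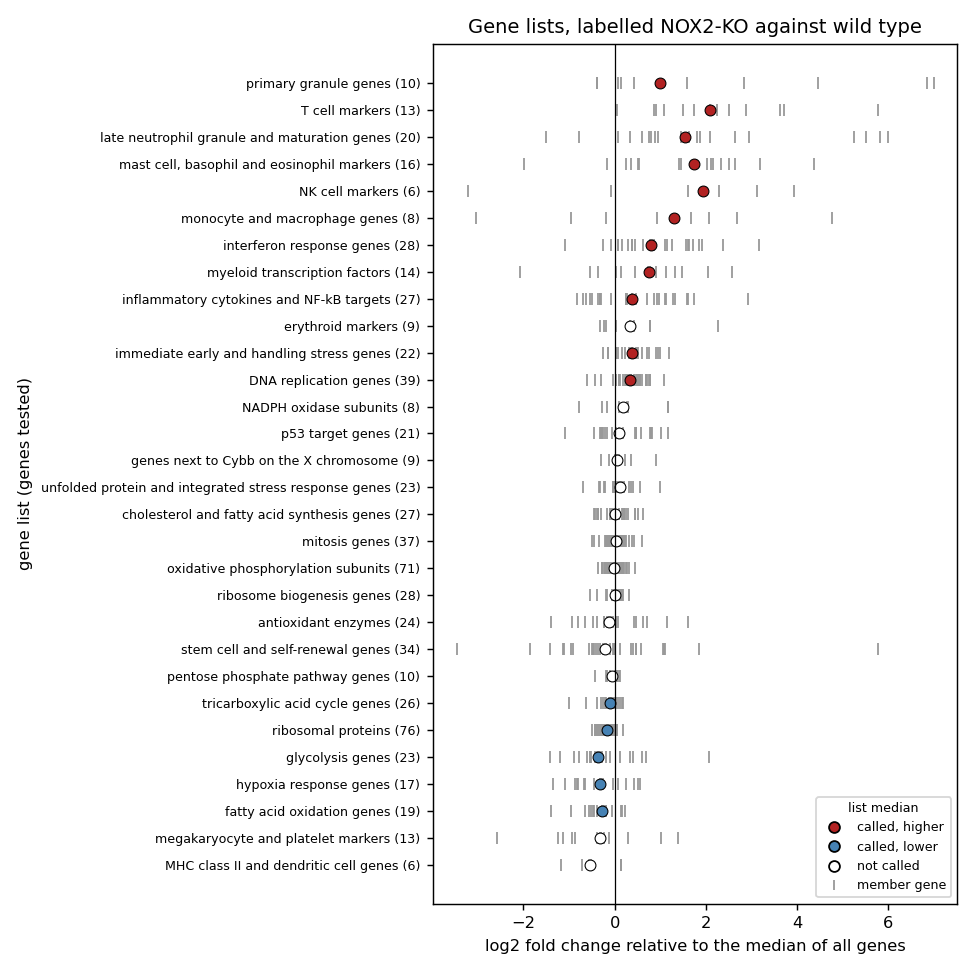
Log2 fold change relative to the median of all tested genes, libraries labelled NOX2-KO against wild type, for the 30 tested lists. Grey ticks are single member genes, circles the list medians, red where camera called the list higher, blue where it called it lower at an adjusted p of 0.05 with a preset correlation, and white where it made no call. The 11 lists called higher include T cell markers with a median of 2.10, the 5 called lower fatty acid oxidation genes with a median of -0.29; the tricarboxylic acid list was not called after TMM scaling.

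Camera called 16 of the 30 lists with its preset correlation, 11 higher and 5 lower, and 0 with the correlation estimated from the 4 libraries, where 4 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.28. That form tests on the 2 residual degrees of freedom, which leaves it little power. Lists with an estimated correlation under 0.01 lost their calls too, among them DNA replication (-0.023), fatty acid oxidation (-0.015) and NF-kB targets (0.004). A call lost in this way therefore cannot be credited to correlation between genes alone, nor does it show that a change is absent. The stem cell, MHC class II, erythroid, antioxidant and ribosome biogenesis lists, which passed under other settings alone, had an adjusted p = 0.636, 0.636, 0.673, 0.893 and 0.893 with an estimated correlation and all libraries. For the mitosis, ribosome biogenesis and cholesterol synthesis lists, which were not called, the median lay 0.03, 0.01 and 0.001 above that of all genes while the direction of the test was lower.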

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

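The protein-coding rescaling was chosen after seeing the data, the other alternatives before. The count of 530 genes stayed within 1.5 times under 7 of the alternatives, from 392 without a variance trend to 656 with protein-coding genes only. It was 1158 at an adjusted p of 0.1 and 0 without a filter on low values, where limma's prior degrees of freedom were lower at 0.9, 3872 genes had an unadjusted p under 0.05 and the cause was not tested. It ran from 0 to 0 with 1 library left out, which leaves 1 residual degree of freedom and assumes that the lone library varies like the other group. The replicate block gave 339 genes and 14 lists, without the glycolysis and ribosomal protein lists. Deviations of same-numbered libraries had a correlation of -0.06 over the tested genes. No shift shared by a replicate number was thus seen over all genes, though 1 in some genes is not excluded. Of the 29 to 33 lists tested under the other camera settings with a preset correlation, 13 to 20 were called, among them 12 to 16 of the 16, while 0 were called with an estimated correlation and 7 by fry, which tests members alone and not against other genes. Of the 77 genes taken by the naming rule that passed, 17 no longer did without a variance trend, 13 with the block, 7 with TMM, 3 with quantile normalization, 2 with protein-coding genes only and 77 both without a filter and with any library left out, and all 77 kept their direction. The 7 lists called by fry were the monocyte, mast cell, interferon, DNA replication, fatty acid oxidation, hypoxia and tricarboxylic acid lists. Fry was run on unscaled values, so the median change of -0.19 over all tested genes counts toward lower lists and against higher ones. The tricarboxylic acid list had a median of only -0.11 relative to all genes, and camera did not call it after TMM scaling. The count tests planned for recovered reads were not run. Depth is not known, so the counting error of genes of low FPKM cannot be given.

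Directions turned in these results, of which only the ribosomal list was called with all libraries, and the cause was not tested. As log2 changes before subtracting the median, Ltf (-0.12) was 0.068 with TMM, 0.006 with quantile normalization, 0.12 with protein-coding genes only and -1.23 to 0.99 with 1 library left out. Cd34 (-0.22) was 0.033 with protein-coding genes only, and with 1 library left out Cyba was -0.21 to 0.35 and Ncf4 -0.018 to 0.22. For lists the values are mean z-scores of members minus other genes, or of members alone for fry. NADPH oxidase subunits (0.18) were -0.43 without a filter, -0.42 at a minimum of 5 FPKM, -0.44 with fry and -0.58 to 0.61 with 1 library left out. The p53 targets were -0.18 with fry, and the neighbours of Cybb -0.30 without a filter, -0.22 with fry and -0.089 to 0.96 with 1 left out. The unfolded protein list was -0.33 without a filter, -0.47 with fry and -0.27 to 0.36 with 1 left out. With TMM, quantile normalization and protein-coding genes only, in that order, oxidative phosphorylation was 0.067, 0.27 and 0.28, cholesterol synthesis 0.068, 0.071 and 0.13, mitosis 0.20, 0.22 and 0.25, and ribosome biogenesis 0.08, 0.20 and 0.20. At a minimum of 5 FPKM cholesterol synthesis was 0.011 and mitosis 0.065. With 1 library left out, oxidative phosphorylation ran from -1.44 to 0.95, cholesterol synthesis from -0.19 to 0.15, mitosis from -0.14 to 0.037, ribosome biogenesis from -0.97 to 0.34, antioxidant enzymes from -1.11 to 0.01, erythroid markers from -0.073 to 1.91 and ribosomal proteins from -1.47 to 0.34.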

Other observations

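All tests in this part were chosen after the results were seen. Several classes of small and ribosomal RNA had a median above that of all genes in the libraries labelled NOX2-KO. The libraries were made from polyadenylated RNA, per the labels, so these values need not follow the amounts of such RNA in the cells. The ribosomal share of FPKM split by group, at 1.25% and 1.78% in wild type against 4.14% and 3.43%. Whether a difference in library preparation gave this was not tested. The median change relative to all genes was 1.78 log2 units over 67 snRNA genes, 0.65 over 134 snoRNA genes, 0.75 over 120 microRNA genes and 1.81 over 11 ribosomal RNA genes, of which 5, 12, 3 and 0 passed as higher and 1, 2, 3 and 0 as lower. It was 0.80 over 14 mitochondrial tRNA genes, of which 1 passed, as lower, and 0.68 over the 13 mitochondrial protein-coding genes, of which none passed. Over 157 lincRNA genes it was 0.11, with 2 higher and 2 lower.

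Of the called rises, 2 of 4 in the primary granule list, 3 of 5 in the late neutrophil list, 5 of 5 in the T cell list and 2 of 3 in the NK cell list were of genes with a wild type mean under 1 FPKM. A single admixed cell population with the same expression in both pools would give all its genes the same ratio between the libraries labelled NOX2-KO. The median log2 ratio of replicate 2 to replicate 1 was -0.81 (SD 0.43) over 4 called primary granule genes and 0.70 (SD 0.56) over 5 called T cell genes. This difference of 1.50 argues against 1 such source of both. It does not bear on a source whose expression differed between the pools. The late neutrophil and NK cell lists, at 0.61 (SD 0.45) and 0.64 (SD 0.29), lay near the T cell list, the 3 medians spanning 0.08 before rounding, so 1 source of these 3 is not excluded, while the 7 called genes of the mast cell, basophil and eosinophil list had a median of -0.14 (SD 0.33). The mean of Cd4, Cd8a, Cd5 and Cd6, which were chosen after their values were seen, was at most 0.011 of Cd3g in the libraries labelled NOX2-KO. Cd3g thus rose with little RNA of these genes, which is no test of mature T cells that lack them. A single source of those 3 lists, several kinds of non-leukaemic progenitors and a change in the leukemic cells cannot be told apart. The unnamed markers of the sort would have had to let such progenitors pass. Of the genes that rose, 51.4% had a wild type mean under 1 FPKM, which each could give. Dilution by non-leukaemic cells would lower Hoxa9, which the leukemia's fusion carries. Hoxa9 lay 0.47 ± 0.20 log2 units (SE) above the median of all genes and did not pass (limma adjusted p = 0.463). A small share of other cells would lower it only slightly, so it cannot decide between them.

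Cybb was higher in the libraries labelled NOX2-KO. A change of the whole X chromosome region around the gene is argued against by its 9 tested neighbours, whose median lay 0.05 log2 units (SD 0.35) from that of all genes. Exchanged labels cannot be told apart from a knockout allele that is still transcribed, since the change of 2.20 log2 units in Cybb is the pattern itself. The primary granule and monocyte lists were also higher in these libraries. Other cells in the pools and a change in the leukemic cells, both left open above, were not tested as sources of the rise of Cybb. No biological explanation was tested.

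Protein-coding genes gave 73.3% and 76.4% of FPKM in the libraries labelled NOX2-KO against 84.7% and 81.3% in wild type, which are shares of FPKM and not of reads. Gain or loss of a whole chromosome was argued against by the medians of the 20 nuclear chromosomes with at least 20 tested genes, the farthest of which lay at -0.04 log2 units from that of all genes.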
